A study of Rattus norvegicus with 16 samples.

How the data were processed

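RNA from knee cartilage of rats (healthy, osteoarthritic, and osteoarthritic treated with HA, cells and drug or with coacervate, cells and drug) was measured in 16 libraries, 4 per group. Library names give the healthy group as Sham and the osteoarthritic group as PBS. Per the labels' protocols, total RNA with a RIN above 7 was selected with oligo(dT) beads, its second strand was marked with dUTP and removed, and fragments were sequenced from both ends on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and genome build rn6 without stating what each did. The counting tool, the gene annotation version and the strand setting are not given, so genes that overlap on opposite strands or share sequence with a near copy are uncertain.

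The deposited table holds, per the file headers, a count and an FPKM value for each of 23552 genes in each library. The counts are whole numbers and were not normalised by the authors, since their totals differ between libraries. The deposited FPKM values were scaled by the authors to gene length and to the number of fragments. Even numbers were commoner than odd ones among low counts (6480 values of 2 and 4576 values of 3), so the mates of a pair look counted separately. Counts and FPKM were proportional across libraries for the 2440 genes with an FPKM above 20 in all 16, and other genes were not compared. There was 1 table, it held no column without a sample, and 972 of its genes shared a symbol with another.

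Before the data were examined, the tests, the gene lists, the alternatives and the rule for naming genes were fixed, with limma on log2(FPKM + 1) as the test and edgeR in its place if the table held counts. It did, so edgeR's quasi-likelihood test on counts was used and limma became an alternative. Genes with an FPKM of at least 1 in at least 4 of the 16 libraries were tested (14337 genes). Libraries were scaled with TMM, 1 fit held the 4 group means, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Values are given as normalised CPM (counts scaled to the effective library size), and log2 levels were computed with a prior count of 2. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and python 3.11.15 were used.

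The comparisons were osteoarthritic against healthy, each treatment against osteoarthritic, the treatments against each other, and each treatment against healthy. For each main comparison the named genes were the 8 largest rises and 8 largest falls among genes that passed, did not overlap between the groups and had a mean FPKM of at least 5 in the higher group. Symbols that stand for unnamed genes were left out. Added to these were up to 4 members with the smallest p in each list called and a panel of markers given whatever its p, and where fewer than 3 genes passed in a direction the 3 with the smallest p. Igfn1, AABR07046707.1 and the genes named in the comparisons with healthy cartilage of the treated groups fell outside this rule. So did members of annotated terms.

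The 28 gene lists covered cartilage matrix, hypertrophic chondrocyte, osteoblast, osteoclast, protease, inflammatory, interferon, macrophage, neutrophil, erythroid, B cell, T cell and NK cell, skeletal muscle, fibrous matrix, tendon, adipocyte, endothelial, stromal, proliferation, senescence, TGF-beta and BMP, Wnt, oxidative phosphorylation, glycolysis and hypoxia, antioxidant, immediate early, secretory pathway and ribosomal protein genes. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. No call held with an estimated correlation in any comparison. Terms of 15 to 500 tested genes, as annotated in the deposited table, were tested with two-sided Fisher's exact tests. The background was the tested genes with an annotation of the same source, 12627 of them for gene ontology (GO). The score of the disease genes was compared between groups by an exact permutation test over 70 assignments.

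The procedure was tested on simulated counts with known changes. For osteoarthritic against healthy it recovered 28.4% of changes of 1.5-fold, 67.2% of 2-fold and 90.9% of 4-fold changes, and for coacervate against HA 17.9%, 73.1% and 95.5%. False calls made up 3.12% and 5.34% of the calls. The simulated genes varied independently of each other, and no simulated libraries stood apart as a set. These shares need not hold for the real libraries, so a gene that did not pass is not shown to be unchanged. Total counts were 36988722 to 50725189 per library. Genes named with few counts carry counting error that is not small beside the spread between replicates, and more so if mates were counted separately. In healthy replicates 1 to 4, Mmp10 had 48, 85, 45 and 52 counts and Ccl7 had 33, 34, 29 and 59. Counts come from amplified fragments without molecular identifiers.

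The alternatives were other scalings, filters, pseudocounts, fold cutoffs, sample weights by 2 estimators, a fit of the compared groups alone, a replicate block and leaving out each library in turn. Chosen after seeing the data were DESeq2, limma at a pseudocount of 1, leaving out osteoarthritic replicates 2 and 3 or coacervate replicates 2 and 3, leaving out haemoglobin genes, the ribosomal protein level as a covariate, the sample weights estimated gene by gene, term tests under each alternative and a reduced disease score. The smallest number of genes a list needed was 5. No genome sequence was at hand, so GC content was not examined.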

Results

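RNA was sequenced from rat knee cartilage in 16 libraries, 4 in each of 4 groups. The groups were healthy cartilage, osteoarthritic cartilage, and osteoarthritic cartilage treated with hyaluronic acid (HA), cells and a drug or with a coacervate, cells and a drug. The library names call the healthy group Sham and the osteoarthritic group PBS, which the sample titles do not explain. Neither group can be taken as untouched. A coacervate is a liquid phase rich in polymer that separates from water and can carry other substances. The labels name neither the drug, the cell type nor the make-up of the coacervate, and they give an age of 10 weeks for every library. Total counts ran from 36988722 (healthy replicate 3) to 50725189 (coacervate replicate 1), and 18627 to 19457 genes had a count above 0 in a library. The labels do not say whether the 4 replicates of a group came from separate animals, which limits every p-value given here.

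Several kinds of cell were present in every library. Haemoglobin transcripts, which come from red blood cells and their precursors, took 10.2% to 22.2% of the counts. Osteoarthritic replicates 2 and 3 stood apart from the other 14 libraries, with positions of 69.6 and 58.9 on the first principal component (32.5% of the variance) against -32.3 to 12.7. Their haemoglobin shares were 22.2% and 21.7%, against 12.6% and 10.2% in osteoarthritic replicates 1 and 4. Their mean log2 levels of the ribosomal protein genes, relative to the mean of the 16 libraries, were 1.0 and 0.83, and those of the other 14 libraries lay between -0.40 and 0.14. Skeletal muscle genes took 1.06% ± 0.154 of the counts in healthy, 0.637% ± 0.187 in osteoarthritic, 0.631% ± 0.0538 in HA-treated and 1.44% ± 0.909 in coacervate-treated cartilage (SD, n = 4), with 2.75% in coacervate replicate 3.

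**Figure D1:**
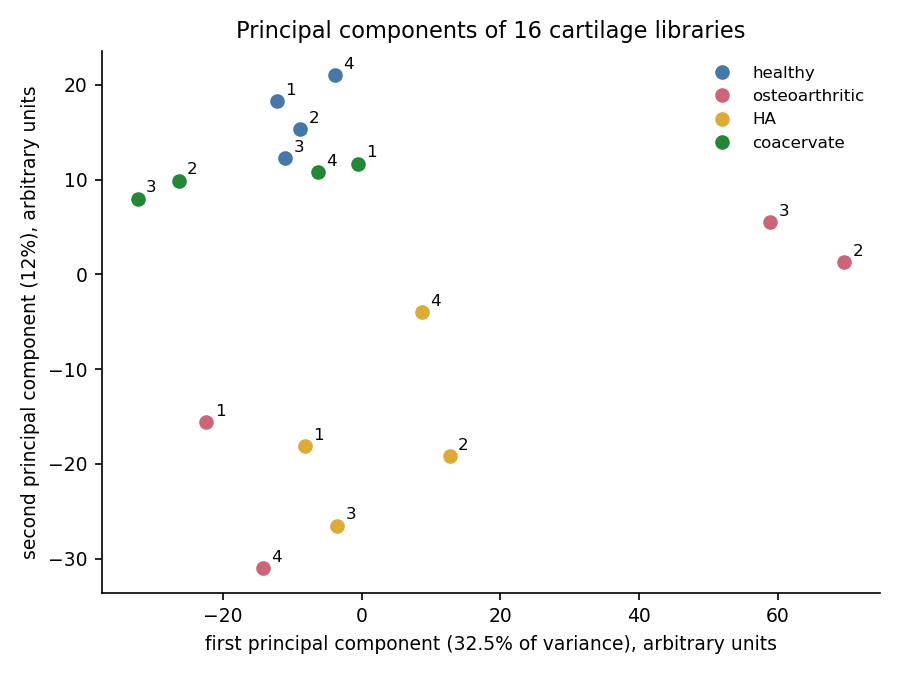
Positions of the 16 libraries on the first and second principal components of log2 CPM, in arbitrary units, with 1 point per library and the replicate number beside it. Osteoarthritic replicates 2 and 3 lie at 69.6 and 58.9 on the first component, and the other 14 libraries lie between -32.3 and 12.7.

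The first comparison asked how osteoarthritic cartilage differed from healthy cartilage. Mmp3 (stromelysin-1, a protease that cuts proteoglycans and several collagens; ENSRNOG00000032626, rn6 chromosome 8, 5676665 to 5698579) rose 11.2-fold (log2 fold change 3.49 ± 0.65 SE, adjusted p = 0.029), from 5.85 ± 1.04 to 65.8 ± 50.6 CPM (SD, n = 4 per group). The chemokine gene Ccl7, whose product attracts monocytes (ENSRNOG00000000239, chromosome 10, 69423086 to 69424979), rose 7.18-fold (2.84 ± 0.48, adjusted p = 0.0194). Trem2, a lipid-sensing receptor of macrophages (ENSRNOG00000013578, chromosome 9, 14611561 to 14618013), rose 5.04-fold (2.33 ± 0.32, adjusted p = 0.0115), and Apoe, a carrier of lipids between cells (ENSRNOG00000018454, chromosome 1, 80612895 to 80617057), rose 4.95-fold from 336 ± 165 to 1660 ± 659 CPM (adjusted p = 0.0115). In all, edgeR called 72 of 14337 tested genes, of which 56 rose and 16 fell, and 2548 had an unadjusted p under 0.05. The 4 osteoarthritic values of 907 genes (6.33%) did not overlap with the 4 healthy values, where chance gives 2.86%.

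Among the other large rises were Mmp10, a related stromelysin (8.97-fold, adjusted p = 0.0498), and the chemokine genes Ccl9 (6.59-fold, adjusted p = 0.0455) and Ccl2 (4.80-fold, adjusted p = 0.0466). Scimp, an adaptor protein of antigen-presenting cells, rose 4.73-fold (adjusted p = 0.0254). The falls were smaller. Sik1, a salt-inducible kinase, fell by 1.10 ± 0.23 on the log2 scale, Gp5, a platelet glycoprotein, by 0.81 ± 0.17, Arrdc3, an arrestin-domain protein, by 0.79 ± 0.14, Adgrg1, an adhesion receptor, by 0.67 ± 0.13 and Cd38, an enzyme that consumes NAD, by 0.61 ± 0.09. A pair of mitochondrial tRNA features, AY172581.7 and AY172581.10, fell by 1.22 and 1.04. The 4 values of each gene named so far in 1 group lay on the same side of the 4 in the other group. Rps27a carried 2 identifiers that moved in opposite directions (-1.59 and 1.97), which leaves its change uncertain. Whether reads were divided between near-identical copies was not tested.

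Of the 25 tested matrix-degrading proteases, 3 rose over all genes (Mmp3, Mmp10 and cathepsin L, Ctsl), and 11 rose and 1 fell adjusted over the list alone. Ctsl, a lysosomal protease, went from 126 ± 8.61 to 241 ± 24.6 CPM (1.91-fold, adjusted p = 0.0115), while Mmp12, macrophage elastase, had a log2 fold change of 2.98 ± 0.68 that did not pass (adjusted p = 0.07). The list had a median log2 fold change of 0.47 and was called by camera (adjusted p = 7.09e-07, and adjusted p = 0.663 with an estimated correlation). Of 28 fibroblast and fibrous matrix genes, 3 rose over all genes and 10 adjusted over the list alone. They included Mfap5, a microfibril protein (1.06 ± 0.20), Cthrc1, a secreted glycoprotein (1.0 ± 0.20), and dermatopontin, Dpt (1.26 ± 0.26), and the list's median was 0.51 (camera adjusted p = 1.09e-07, and adjusted p = 0.663 with an estimated correlation). Without osteoarthritic replicate 4 the fibrous matrix median was 0.305. Of 21 macrophage genes, Trem2 rose over all genes, and 8 rose and 1 fell adjusted over the list alone (median 0.33, camera adjusted p = 3.17e-05, adjusted p = 0.457 with an estimated correlation). The fractalkine receptor gene Cx3cr1 (1.06 ± 0.26, adjusted p = 0.0861) and the endotoxin co-receptor gene Cd14 (1.04 ± 0.26, adjusted p = 0.0906) did not pass over all genes. The limma rotation test fry called the macrophage list and no other (adjusted p = 0.0458). Of 24 inflammatory mediators, Ccl2 and Ccl7 rose and 22 did not pass (median 0.05, camera adjusted p = 0.114).

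B cell genes were lower in osteoarthritic cartilage, with 16 of 19 negative and a median of -0.49 (camera adjusted p = 1.53e-07, and adjusted p = 0.663 with an estimated correlation). None fell over all genes and 8 fell adjusted over the list alone, with Pax5, a B cell transcription factor, at -1.03 ± 0.24 (adjusted p = 0.0736). The groups overlapped in mean log2 B cell level. Osteoarthritic replicates 1 to 3 lay at -0.107, -0.147 and -0.123, above healthy replicate 4 at -0.353, and osteoarthritic replicate 4 lay at -0.946. The exact permutation p of the B cell level was 0.114 (0.4 adjusted over the lists). Skeletal muscle genes were lower in 21 of 22 (median -0.69, camera adjusted p = 7.92e-07, and adjusted p = 0.663 with an estimated correlation). Adipocyte genes had a median of -0.26 (camera adjusted p = 0.00727) and tendon and ligament genes 0.38 (adjusted p = 0.00898), with 3 risen adjusted over the list alone, among them tenomodulin, Tnmd (1.05 ± 0.26). Secretory pathway genes had a median of 0.16 (camera adjusted p = 0.00285), with the collagen chaperone gene Serpinh1 at 0.49 ± 0.15. With an estimated correlation each of these 3 lists had an adjusted p = 0.663. Camera did not call the adipocyte list without osteoarthritic replicate 4 (median -0.11, adjusted p = 0.794), nor the tendon list without osteoarthritic replicate 1 or 4 (0.36 and 0.42, adjusted p = 0.208 and 0.11). The secretory median was 0.10 without osteoarthritic replicate 2, and camera did not call that list without osteoarthritic replicates 2 and 3.

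Ribosomal protein genes were higher in 57 of 57 (median 0.49, camera adjusted p = 1e-08, and adjusted p = 0.663 with an estimated correlation), and oxidative phosphorylation genes in 57 of 61 (median 0.37, adjusted p = 2.11e-07, and adjusted p = 0.663 with an estimated correlation). No member of either list passed over all genes. Neutrophil genes were higher in 20 of 21 (median 0.42, camera adjusted p = 0.000969), and antioxidant genes in 19 of 23 (median 0.29, adjusted p = 0.00896), both with an adjusted p = 0.663 with an estimated correlation. These 4 lists turned with the libraries that stood apart. Without osteoarthritic replicates 2 and 3 their medians were -0.27 (ribosomal), -0.20 (oxidative phosphorylation), -0.079 (neutrophil) and -0.097 (antioxidant), while the protease, fibrous matrix and B cell medians were 0.75, 0.97 and -0.63. That B cell median rested on osteoarthritic replicates 1 and 4, with B cell levels of -0.107 and -0.946. Without osteoarthritic replicate 2 alone, the ribosomal and oxidative phosphorylation medians were 0.245 and 0.22, and camera did not call neutrophil genes (0.11, adjusted p = 0.209). It did not call antioxidant genes without osteoarthritic replicate 2 or 3 (0.24 and 0.205, adjusted p = 0.0692 and 0.0884).

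Genes that mark cartilage itself did not pass. Col2a1, the main cartilage collagen, had a log2 fold change of 0.11 ± 0.32 (adjusted p = 0.876), and Acan, the core protein of aggrecan, 0.12 ± 0.35 (adjusted p = 0.873). Prg4 (lubricin) was at 0.92 ± 0.37 (adjusted p = 0.228), Comp, a matrix protein that binds collagen, at 0.75 ± 0.22 (adjusted p = 0.166), Mmp13, the main collagenase of cartilage, at -0.64 ± 0.23 (adjusted p = 0.205) and the aggrecanase gene Adamts5 at 0.32 ± 0.25. The chondrocyte transcription factor gene Sox9 (-0.56), the hypertrophy marker Col10a1 (0.02), the type I collagen gene Col1a1 (0.15) and the cytokine gene Il1b (0.56) did not pass either, and Il6 was too low to be tested. The cartilage matrix list had a median of 0.15 (camera adjusted p = 0.154). The remaining lists were not called. Their medians and camera adjusted p were -0.038 (0.235) for hypertrophic chondrocyte, -0.023 (0.503) for osteoblast and osteocyte, -0.099 (0.132) for osteoclast, 0.17 (0.503) for interferon response and 0.17 (0.428) for erythroid genes. They were 0.10 (0.404) for T cell and NK cell, -0.16 (0.159) for endothelial, -0.0096 (0.209) for mesenchymal stromal cell, 0.038 (0.743) for proliferation and 0.034 (0.302) for senescence genes. They were -0.037 (0.242) for TGF-beta and BMP signalling, -0.093 (0.743) for Wnt signalling, 0.031 (0.989) for glycolysis and hypoxia and -0.13 (0.132) for immediate early and heat shock genes.

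Fisher's exact test called 11 annotated terms among the 56 genes that rose, of which 55 carried a GO annotation. The extracellular region held 16 of them where 1.94 were expected (adjusted p = 7.54e-08), and neutrophil chemotaxis held 5 where 0.183 were expected (Ccl2, Ccl7, Ccl9, Lgals3 and LOC108348047, adjusted p = 0.00101). The other 9 terms covered cytokine and chemokine activity, responses to interferon-gamma and interleukin-1, ERK signalling, chemotaxis, extracellular matrix, Wnt-protein binding and the annexins Anxa2, Anxa4 and Anxa5. Ccl2, Ccl7 and Ccl9 were members of both chemotaxis terms and of those for cytokine and chemokine activity, interferon-gamma, interleukin-1 and ERK signalling. These terms are therefore not separate results. The terms depended on single libraries. Over all comparisons 16 were called, and these were 1, 0, 4 and 1 without healthy replicates 1 to 4, 214, 5 and 89 without osteoarthritic replicates 1, 3 and 4, 6, 7 and 1 without HA replicates 1 to 3, 3 and 2 without coacervate replicates 1 and 2, and 2 with a replicate block. The count of 72 was 8 in a fit of the 8 libraries of these groups alone, 26 with a replicate block, 164 without osteoarthritic replicates 2 and 3, 21 in limma at a pseudocount of 1 and 418 in DESeq2. It was 23, 15, 18 and 15 without healthy replicates 1, 2, 3 and 4, 25 without osteoarthritic replicate 3 and 1122 without osteoarthritic replicate 1. Libraries outside the comparison, which enter through the shared spread, also moved it, to 44 without HA replicate 1 or 3 and to 38 and 36 without coacervate replicates 1 and 2.

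**Figure D2:**
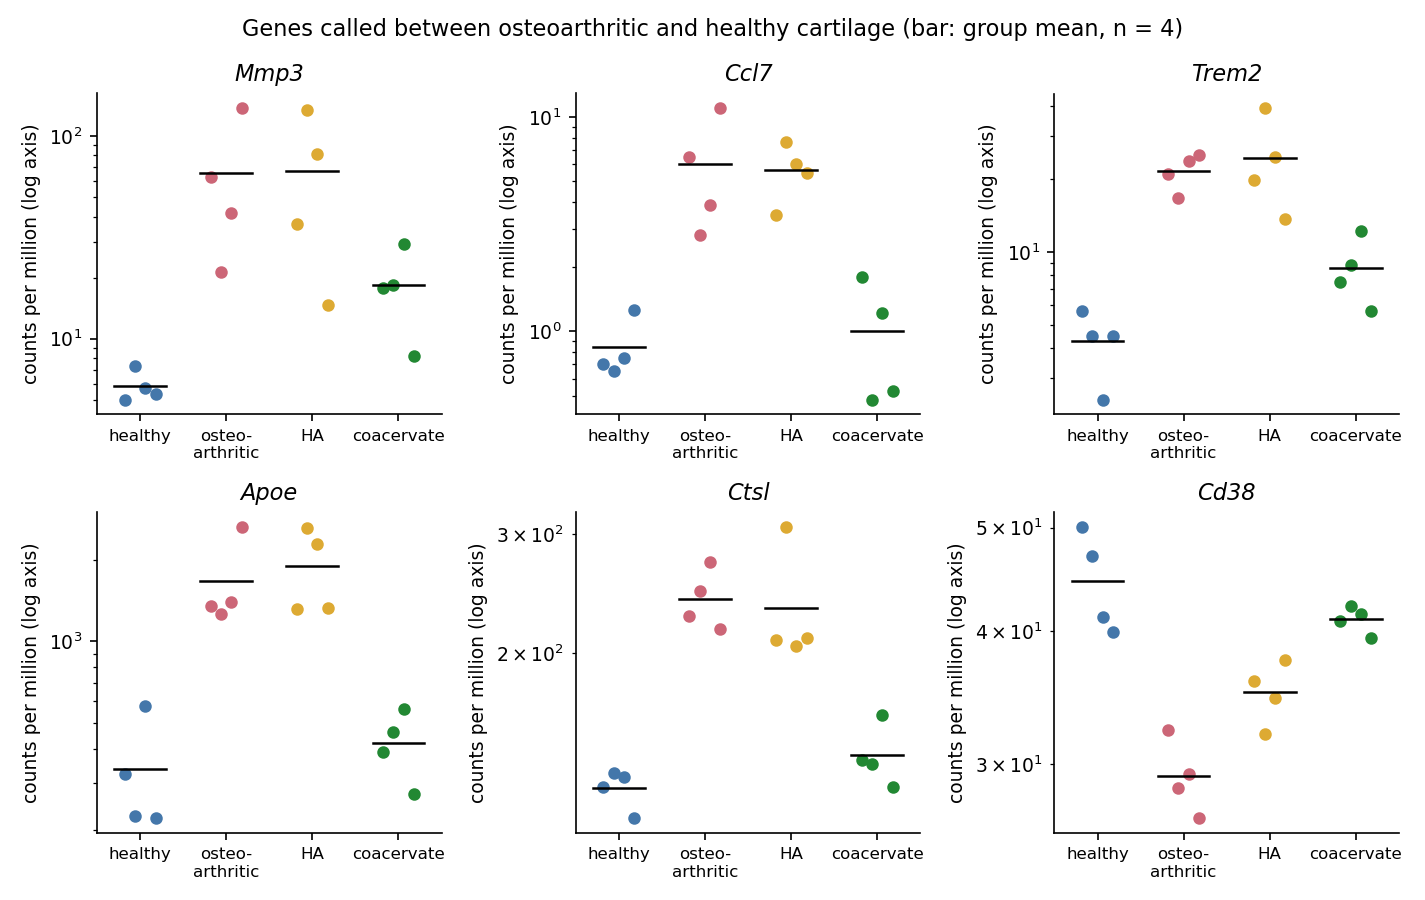
Normalised CPM (log axis) of 6 genes called between osteoarthritic and healthy cartilage, with 1 point per library and a bar at each group mean. Mean Apoe values are 336 in healthy, 1660 in osteoarthritic, 1890 in HA-treated and 422 in coacervate-treated cartilage.

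The second comparison asked what treatment with HA, cells and drug changed in osteoarthritic cartilage. No gene passed the edgeR test, 909 had an unadjusted p under 0.05, the smallest adjusted p was 0.562, and limma at a pseudocount of 1 called 1 and DESeq2 called 8. Of the 72 genes of the disease change, 56 had the opposite sign and 7 passed adjusted over the list alone, with medians of -0.11 for the raised and 0.39 for the lowered genes. The same osteoarthritic libraries served to choose these genes, which favours the opposite sign. Mmp3 stood at 66.9 ± 52.9 CPM after HA treatment and 65.8 ± 50.6 CPM without it (0.02 ± 0.58, adjusted p = 0.994, n = 4). The genes with the smallest p, none of which passed, were Rps18l1 (0.73 ± 0.15), Csrnp1 (0.40 ± 0.11) and Ccdc142 (0.51 ± 0.15) on the higher side. On the lower side they were catalase, Cat (-0.60 ± 0.13), the erythroblast hormone gene Erfe (-0.79 ± 0.19) and Gimap4, a GTPase of lymphocytes (-0.84 ± 0.21), with adjusted p from 0.69 to 0.745. No cartilage marker passed, with Col2a1 at 0.22 ± 0.32, Acan at 0.11 ± 0.35, Prg4 at 0.13 ± 0.36, Comp at 0.02 ± 0.22, Sox9 at 0.35 ± 0.33, Col10a1 at 0.04 ± 0.46, Mmp13 at 0.14 ± 0.22, Adamts5 at -0.06 ± 0.25, Col1a1 at 0.20 ± 0.32 and Il1b at -0.50 ± 0.32.

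Camera called 7 of the 28 lists between HA-treated and osteoarthritic cartilage. B cell genes were higher in 16 of 19 (median 0.34, adjusted p = 1.2e-08), with the recombinase gene Rag1 at 0.88 ± 0.29 and the surrogate light chain gene Vpreb3 at 1.13 ± 0.41. Oxidative phosphorylation genes were lower in 59 of 61 (median -0.36, adjusted p = 2.41e-12) and ribosomal protein genes in 55 of 57 (median -0.40, adjusted p = 5.64e-09). Antioxidant (median -0.22), erythroid (-0.21), adipocyte (-0.22) and T cell and NK cell genes (-0.24) were also lower (adjusted p = 0.00719, 0.00639, 0.0205 and 0.0354). The haemoglobin share was 11.1% to 12.5% in the HA-treated libraries and 12.6%, 22.2%, 21.7% and 10.2% in osteoarthritic replicates 1 to 4. With an estimated correlation all 7 had an adjusted p = 0.985. Cat was the only member of these lists to pass adjusted over the list alone. Without osteoarthritic replicates 2 and 3, the B cell median was 0.54, and it rested on osteoarthritic replicates 1 and 4 (B cell levels -0.107 and -0.946). In that setting the medians turned to 0.37 for ribosomal protein and 0.24 for oxidative phosphorylation genes. The means of the antioxidant, adipocyte and T cell and NK cell lists turned as well, to 0.0926, 0.017 and 0.00291, and camera called none of these 3 nor the erythroid list. Single libraries ended 5 of the 7 calls by camera. Ribosomal protein genes were not called without osteoarthritic replicate 2 (median -0.15, adjusted p = 0.334), antioxidant genes without osteoarthritic replicate 2 or 3 (-0.16 and -0.14, adjusted p = 0.121 and 0.143) and erythroid genes without HA replicate 1 (-0.16, adjusted p = 0.137). Adipocyte genes were not called without HA replicate 3 or osteoarthritic replicate 1 or 3 (-0.20, -0.21 and -0.14, adjusted p = 0.066, 0.359 and 0.768). T cell and NK cell genes were not called without HA replicate 3 or 4 or osteoarthritic replicate 1 or 2 (-0.26, -0.25, -0.31 and -0.21, adjusted p = 0.206, 0.338, 0.122 and 0.341). Other medians moved and stayed called. Without osteoarthritic replicate 4 they were 0.20 (B cell) and -0.45 (adipocyte), without replicate 1 -0.615 (ribosomal) and -0.36 (antioxidant), without replicate 2 -0.20 (oxidative phosphorylation), and without replicate 3 -0.235 (oxidative phosphorylation), -0.25 (ribosomal) and -0.14 (erythroid). For T cell and NK cell genes they were -0.375 and -0.51 without HA replicates 1 and 2.

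The third comparison asked what treatment with the coacervate, cells and drug changed in osteoarthritic cartilage. Here 21 genes passed in edgeR, of which 18 fell and 3 rose, and 3131 had an unadjusted p under 0.05. Apoe fell by 1.98 ± 0.36 on the log2 scale, from 1660 ± 659 to 422 ± 122 CPM, and Ccl7 fell by 2.59 ± 0.47, from 6.05 ± 3.64 to 1.0 ± 0.621 CPM (SD, n = 4 per group). The immunoglobulin receptor gene Fcgr2a fell by 1.07 ± 0.17, the lipid-binding Fabp5 by 1.19 ± 0.21, the lectin receptor gene Clec4a2 by 1.06 ± 0.18, the myeloid receptor gene Cd300le by 0.97 ± 0.17 and Ctsl by 0.77 ± 0.13. The GTPase gene Arl11 fell by 0.99 ± 0.19 and the phosphodiesterase gene Smpdl3a by 0.98 ± 0.16. Adgrg1, which had fallen in osteoarthritic cartilage, rose by 0.74 ± 0.13. Each of these genes had an adjusted p of 0.0497, with no overlap between the 4 values of the groups. The other 2 that rose, named here after their values were seen, were Igfn1 (2.47), expressed in skeletal muscle, and AABR07046707.1 (0.69).

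All 21 genes had the sign opposite to their change between osteoarthritic and healthy cartilage, and 16 of the 21 were called there. The same 4 osteoarthritic libraries entered both comparisons with opposite sign, which produces such a reversal in part by itself. The count of 21 was 0 in a fit of the 8 libraries of these groups alone, 0 in limma at a pseudocount of 1, 15 in limma with quantile scaling, 0 without coacervate replicates 2 and 3, 3 without osteoarthritic replicates 2 and 3 and 797 in DESeq2. It was also 0 with a replicate block and without any single coacervate library or osteoarthritic replicate 2 or 3, and 2054 and 1368 without osteoarthritic replicates 1 and 4. Libraries outside the comparison moved it as well, to 0 without any single healthy library or HA replicate 1, to 1 without HA replicate 3 and to 7 without HA replicate 4.

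Camera called 13 lists in this comparison. Of 21 neutrophil genes, 20 were lower, and 17 fell adjusted over the list alone (median -0.78, adjusted p = 7.59e-11, and adjusted p = 0.492 with an estimated correlation), with the calcium-binding S100a8 at -1.72 ± 0.42 and the antimicrobial peptide gene Camp at -1.35 ± 0.36. Of 21 macrophage genes, 6 fell adjusted over the list alone (median -0.34, adjusted p = 0.000385, and adjusted p = 0.492 with an estimated correlation), and Trem2 (-1.33 ± 0.31, adjusted p = 0.0924) and lysozyme, Lyz2 (-0.85 ± 0.21, adjusted p = 0.0955), did not pass over all genes. Of 24 inflammatory mediators, Ccl7 fell over all genes, and 2 fell adjusted over the list alone (median -0.29, adjusted p = 0.0028, and adjusted p = 0.511 with an estimated correlation), with Ccl2 at -2.39 ± 0.47 (adjusted p = 0.0635). Of 25 proteases, Ctsl fell and the median was -0.25 (adjusted p = 0.00503, and adjusted p = 0.792 with an estimated correlation), while Mmp3 was at -1.84 ± 0.60 (adjusted p = 0.137). Skeletal muscle genes were higher in 22 of 22, and 17 rose adjusted over the list alone (median 0.96, adjusted p = 2.49e-11, and adjusted p = 0.494 with an estimated correlation). B cell genes had a median of 0.41 (adjusted p = 0.000161, and adjusted p = 0.611 with an estimated correlation), with 4 risen adjusted over the list alone. Camera did not call the B cell list without osteoarthritic replicate 4 (median 0.24, adjusted p = 0.137), which had the lowest B cell level of the 16 libraries (-0.946), nor the inflammatory list (-0.24, adjusted p = 0.15). It did not call the proteases without coacervate replicate 4 or osteoarthritic replicate 1 or 4 (-0.18, -0.18 and -0.19, adjusted p = 0.0987, 0.209 and 0.251). The muscle median was 0.59 without coacervate replicate 3, and the neutrophil median -0.47 without osteoarthritic replicate 2.

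Ribosomal protein genes were lower in 56 of 57 (median -0.53, camera adjusted p = 4.38e-09, and adjusted p = 0.792 with an estimated correlation), and oxidative phosphorylation genes in 54 of 61 (median -0.41, adjusted p = 6.91e-06, and adjusted p = 0.793 with an estimated correlation). Without osteoarthritic replicates 2 and 3 these medians turned to 0.25 and 0.22, while the neutrophil, macrophage and muscle medians were -0.25, -0.21 and 1.02. T cell and NK cell genes (median -0.62, adjusted p = 0.000349, and adjusted p = 0.494 with an estimated correlation) and secretory pathway genes (-0.24, adjusted p = 0.000349, and adjusted p = 0.511 with an estimated correlation) were lower. So were antioxidant genes (-0.23, adjusted p = 0.00778, and adjusted p = 0.611 with an estimated correlation), whose mean turned to 0.0695 without osteoarthritic replicates 2 and 3. Endothelial (0.23, adjusted p = 0.0283) and proliferation genes (0.15, adjusted p = 0.00876) were higher, both with an adjusted p = 0.793 with an estimated correlation. Camera did not call endothelial genes without coacervate replicate 2 or 3 or osteoarthritic replicate 2 or 4 (0.20, 0.105, 0.14 and 0.22, adjusted p = 0.0643, 0.227, 0.07 and 0.0927), and their median was 0.36 without osteoarthritic replicate 1. The endothelial call was lost in 16 of 35 alternatives, among them limma at each pseudocount, library totals (adjusted p = 0.054) and a stricter filter (adjusted p = 0.164). The mean of the list reversed in 2 more, to -0.25 with no filter and -0.0234 without coacervate replicates 2 and 3. Camera did not call proliferation genes without coacervate replicate 1 or 4 or osteoarthritic replicate 1 (0.091, 0.145 and 0.10, adjusted p = 0.306, 0.0783 and 0.362). Without osteoarthritic replicate 2 the ribosomal and oxidative phosphorylation medians were -0.28 and -0.22, without replicate 3 the latter was -0.26, and without replicate 1 the antioxidant median was -0.38. No cartilage marker passed, with Col2a1 at -0.28 ± 0.32, Acan at -0.09 ± 0.35, Prg4 at 0.22 ± 0.36, Comp at 0.22 ± 0.22, Sox9 at 0.58 ± 0.33, Col10a1 at -0.75 ± 0.47, Mmp13 at -0.03 ± 0.22, Adamts5 at -0.21 ± 0.25, Col1a1 at 0.04 ± 0.32 and Il1b at -0.81 ± 0.32.

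The fourth comparison set the treatments against each other. No gene passed the edgeR test between coacervate-treated and HA-treated cartilage, although 1485 had an unadjusted p under 0.05 and the 4 values of 1392 genes (9.71%) did not overlap, where chance gives 2.86%. The smallest adjusted p, 0.101, was that of Apoe, at 422 ± 122 CPM with the coacervate and 1890 ± 669 CPM with HA (-2.16 ± 0.36, n = 4), and of the keratin gene Krt75 (-1.61 ± 0.28) and Fcgr2a (-0.99 ± 0.17). Ccl7 (-2.49 ± 0.47, adjusted p = 0.108), Ctsl (-0.73 ± 0.13, adjusted p = 0.108), Trem2 (-1.50 ± 0.31, adjusted p = 0.138), Ccl2 (-2.15 ± 0.47, adjusted p = 0.138) and Mmp3 (-1.86 ± 0.60, adjusted p = 0.232) were lower with the coacervate and did not pass. On the higher side the smallest p belonged to the glycogen-targeting subunit gene Ppp1r3c (1.29 ± 0.27), Apold1 (1.28 ± 0.28) and the poly(A)-binding protein gene Pabpc4 (0.39 ± 0.09), each with an adjusted p of 0.138. Limma at a pseudocount of 1 called 0 genes and DESeq2 called 325, and edgeR called 149 without osteoarthritic replicates 2 and 3. Those 2 libraries enter this comparison only through the filter, the scaling and the spread shared by all groups. EdgeR called 11 without HA replicate 4 and 0 in a fit of the 8 libraries alone.

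Camera called 15 lists between the treatments. Skeletal muscle genes were higher with the coacervate in 22 of 22, and 21 rose adjusted over the list alone (median 1.15, adjusted p = 7.37e-26, and adjusted p = 0.146 with an estimated correlation), with troponin T, Tnnt3, at 1.30 ± 0.31 and creatine kinase, Ckm, at 1.22 ± 0.30. Without coacervate replicate 3 the muscle median was 0.68. Neutrophil genes were lower in 21 of 21, and 8 fell adjusted over the list alone (median -0.59, adjusted p = 4.42e-17, and adjusted p = 0.146 with an estimated correlation), with lipocalin 2, Lcn2, at -0.77 ± 0.21. Proteases (median -0.30) and macrophage genes (-0.27) each had 4 members that fell adjusted over the list alone (adjusted p = 2.39e-06 and 4.08e-05, and adjusted p = 0.349 and 0.183 with an estimated correlation), and inflammatory mediators (-0.28) had 2 (adjusted p = 0.000165, and adjusted p = 0.337 with an estimated correlation). Secretory pathway genes had a median of -0.17 (adjusted p = 3.31e-05, and adjusted p = 0.337 with an estimated correlation), with the chaperone gene Hspa5 at -0.41 ± 0.14. Erythroid genes were higher in 18 of 19 (0.32, adjusted p = 1.55e-05, and adjusted p = 0.349 with an estimated correlation), with the red cell anion exchanger gene Slc4a1 at 0.43 ± 0.18. The protease median was -0.195 without HA replicate 2 and the inflammatory median -0.18 without coacervate replicate 4.

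Proliferation (median 0.12, adjusted p = 0.00211), adipocyte (0.22, adjusted p = 0.0115) and endothelial genes (0.21, adjusted p = 0.0173) were higher with the coacervate, each with an adjusted p = 0.72 with an estimated correlation. Immediate early genes were also higher (0.29, adjusted p = 0.0234, and adjusted p = 0.735 with an estimated correlation), with Fosb at 3.32 ± 0.98 and 49.0 ± 70.5 CPM across the coacervate libraries. Camera did not call them without coacervate replicate 3 (median -0.056, adjusted p = 0.801) or HA replicate 3 or 4 (0.31 and 0.22, adjusted p = 0.0615 and 0.165). Cartilage matrix (-0.23, adjusted p = 0.0147), osteoclast (-0.22, adjusted p = 0.0188), T cell and NK cell (-0.32, adjusted p = 0.0147) and ribosomal protein genes (-0.13, adjusted p = 0.0233) were lower, with adjusted p = 0.709, 0.709, 0.614 and 0.766 with an estimated correlation. Single libraries also ended the camera calls of 6 further lists. These were proliferation genes without coacervate or HA replicate 1 (0.051 and 0.057, adjusted p = 0.217 and 0.0618), endothelial genes without coacervate replicate 2 or 3 or HA replicate 4 (0.18, 0.11 and 0.15, adjusted p = 0.0611, 0.302 and 0.0718) and cartilage matrix genes without coacervate replicate 2 or HA replicate 3 (-0.155 and -0.21, adjusted p = 0.0578 and 0.141). They were also osteoclast genes without coacervate replicate 3 or HA replicate 1 (-0.175 and -0.11, adjusted p = 0.187 and 0.12) and T cell and NK cell genes without coacervate replicate 1 or HA replicate 1 or 2 (-0.21, -0.10 and -0.21, adjusted p = 0.102, 0.0548 and 0.161). Last were ribosomal protein genes without coacervate replicate 2 or 3 or HA replicate 2 or 4 (-0.091, -0.079, -0.090 and -0.12, adjusted p = 0.121, 0.443, 0.145 and 0.144), with a median of -0.225 without coacervate replicate 1. Of 35 alternatives, 13 lost the call of osteoclast genes, 12 that of immediate early genes, 9 that of T cell and NK cell genes, 8 that of ribosomal protein genes, 7 that of cartilage matrix genes and 6 that of endothelial genes, and the last list reversed in 2 more, as did ribosomal protein genes. The cartilage list held chondromodulin, Cnmd, at -0.83 ± 0.36 and Col9a2, a minor cartilage collagen, at -0.73 ± 0.35. No marker of the panel passed, with Col2a1 at -0.50 ± 0.32, Acan at -0.20 ± 0.35, Prg4 at 0.09 ± 0.36, Comp at 0.20 ± 0.22, Sox9 at 0.23 ± 0.33, Col10a1 at -0.80 ± 0.47, Mmp13 at -0.17 ± 0.22, Adamts5 at -0.15 ± 0.25, Col1a1 at -0.16 ± 0.32 and Il1b at -0.31 ± 0.32. Median, mean and test differed in sign for several lists with no call, among them B cell, oxidative phosphorylation, senescence and Wnt genes in this comparison. The same held for adipocyte, Wnt and glycolysis genes in the coacervate against osteoarthritic cartilage and for osteoclast, stromal, proliferation, senescence, hypertrophic and TGF-beta genes in HA-treated against osteoarthritic cartilage.

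**Figure D3:**
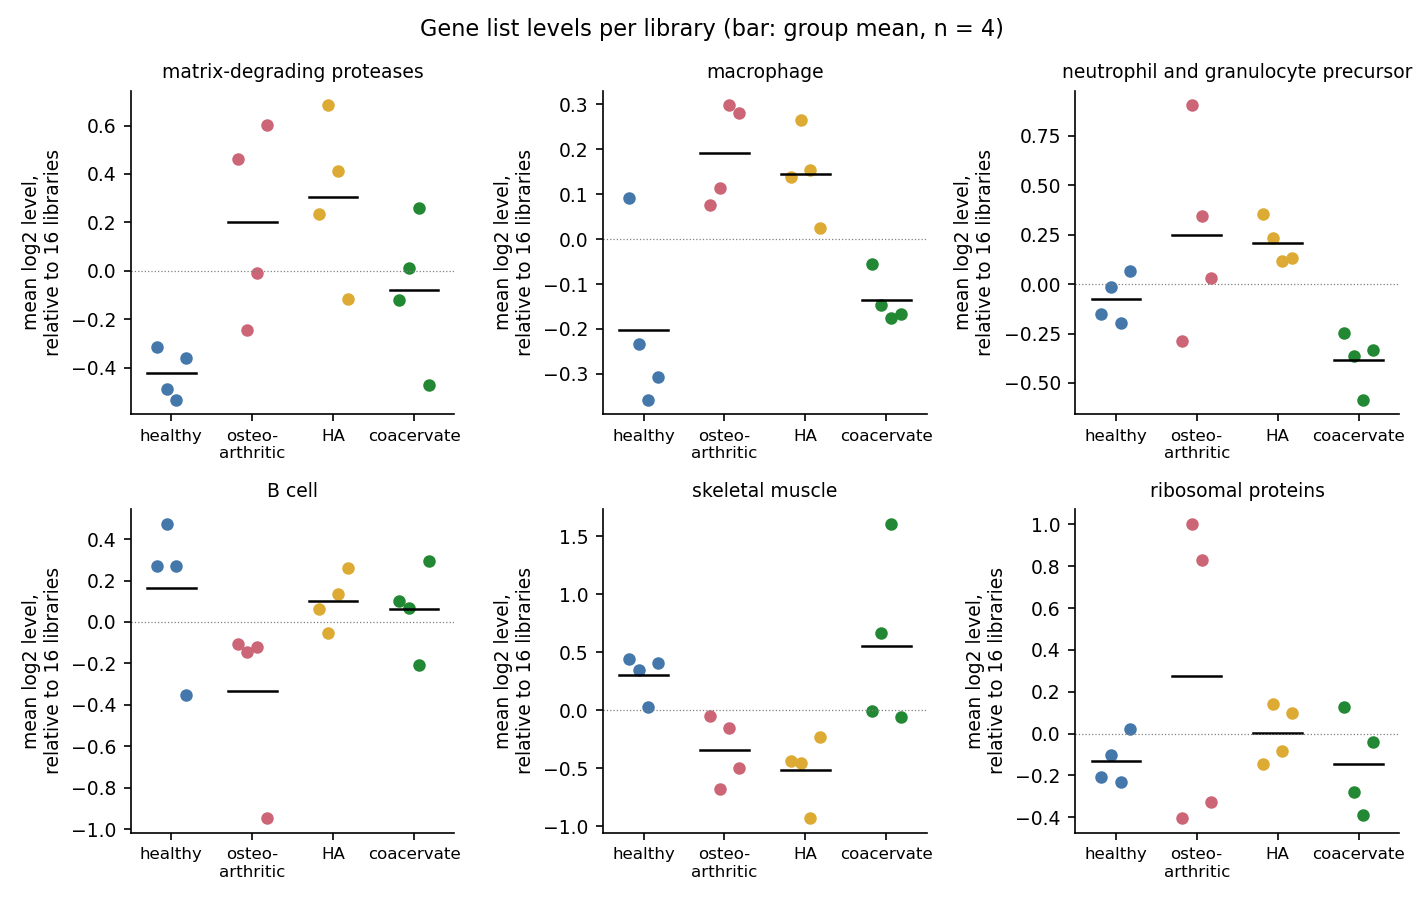
Mean log2 level of 6 gene lists in each of the 16 libraries, relative to the mean of the 16, with 1 point per library and a bar at each group mean. Osteoarthritic replicates 2 and 3 stand at 1.0 and 0.83 for ribosomal protein genes, and the 4 coacervate-treated libraries lie below the 4 HA-treated ones for neutrophil genes.

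The genes that separated osteoarthritic from healthy cartilage were then followed in the treated groups, as a score per library. It was the mean log2(FPKM + 1) of the 56 raised genes minus that of the 16 lowered genes, on the deposited FPKM without TMM scaling. The score was -0.477 ± 0.136 in healthy, 1.45 ± 0.169 in osteoarthritic, 0.951 ± 0.355 in HA-treated and 0.111 ± 0.116 in coacervate-treated cartilage (SD, n = 4). HA-treated cartilage lay at 74.1% and coacervate-treated cartilage at 30.5% of the way from healthy to osteoarthritic. Both ends are libraries on which the genes were chosen, so other groups tend to fall between them, and neither position is a test. The coacervate libraries lay 0.84 below the HA libraries, with no overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). Without coacervate replicate 1, 2 or 4 the differences were -0.841, -0.826 and -0.8, each with an exact permutation p = 0.0571. Each omission ended the call, although the groups still did not overlap and the difference hardly moved. The exact p of 3 against 4 libraries moves in coarse steps. The treated libraries entered the choice of the genes only through the filter on low values, the scaling and the spread shared by all groups. A fit of the 8 healthy and osteoarthritic libraries alone called too few genes for a score, so the 100 with the smallest p in each direction were taken as planned, and with these the difference was -0.982 (exact permutation p = 0.0286). Against osteoarthritic cartilage, whose libraries did take part, the differences were -1.34 for the coacervate (exact permutation p = 0.0286) and -0.498 for HA (p = 0.0571, permutation).

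Gene by gene, 67 of the 72 had the sign opposite to the disease change between coacervate and HA. Of these 72 genes, 45 passed adjusted over the list alone, each opposite to the disease change, and 0 passed over all genes. The median was -0.607 for the raised and 0.238 for the lowered genes. With genes that were in the macrophage, protease or inflammatory lists or were called in another comparison left out, the score of 27 raised and 13 lowered genes differed by -0.513 (exact permutation p = 0.0286). With the libraries paired by replicate number as a block, the difference of -0.84 had an exact p of 0.125, the smallest that 4 pairs can give. Without osteoarthritic replicates 2 and 3 in the choice of genes it was -0.475 (exact permutation p = 0.0571), and without osteoarthritic replicate 1 it was -0.421 (p = 0.0286, permutation).

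**Figure D4:**
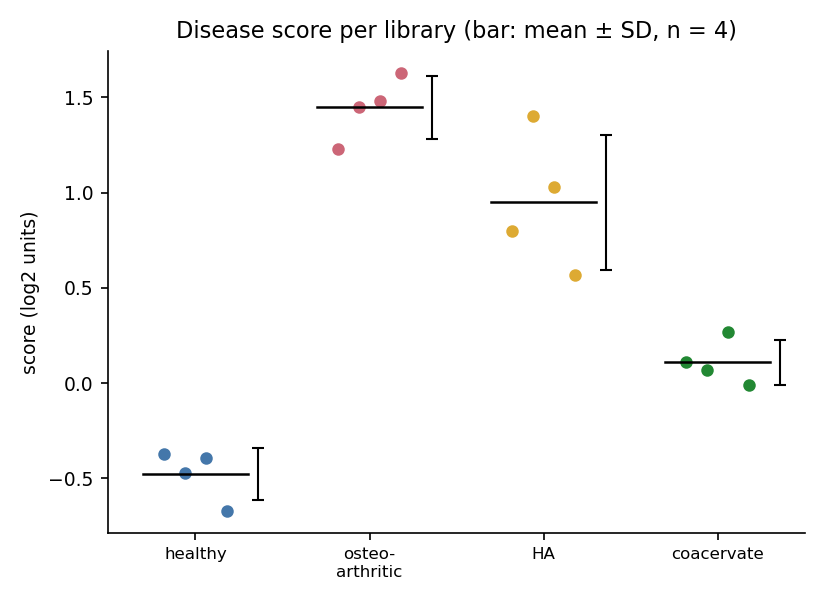
Score of the genes called between osteoarthritic and healthy cartilage (mean log2(FPKM + 1) of raised genes minus that of lowered genes), with 1 point per library and a bar at the group mean ± SD (n = 4). The coacervate-treated libraries (mean 0.111) lie between the healthy (-0.477) and HA-treated libraries (0.951).

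Against healthy cartilage, HA-treated cartilage had 21 genes that rose and 2 that fell in edgeR, with 1183 at an unadjusted p under 0.05. Of these 23 genes, 22 were also called between osteoarthritic and healthy cartilage, all in the same direction, with the same 4 healthy libraries in both comparisons. Mmp3 (3.51 ± 0.65, adjusted p = 0.0453), Ccl9 (3.30 ± 0.56), Ccl7 (2.75 ± 0.48), Trem2 (2.50 ± 0.33, adjusted p = 0.0158) and Apoe (2.49 ± 0.36) rose, as did the lectin gene Lgals3 (1.11 ± 0.19). The Notch target gene Hes1 fell by 1.04 ± 0.19 and Arrdc3 by 0.78 ± 0.14. Terms for the extracellular region (9 genes, 0.74 expected), neutrophil chemotaxis, ERK signalling and response to interleukin-1 were called among the genes that rose. Each of these terms held Ccl7 and Ccl9. The 16 terms called over all comparisons were 1, 0, 4 and 1 without healthy replicates 1 to 4, and 6, 7 and 1 without HA replicates 1 to 3. Camera called 10 lists and 0 with an estimated correlation. The count of 23 was 0 with a replicate block, 14 in limma at a pseudocount of 1, 94 without osteoarthritic replicates 2 and 3, 159 in DESeq2 and 390 in a fit of the 8 libraries alone. It was 2, 0, 2 and 0 without healthy replicates 1, 2, 3 and 4, and 14, 1 and 0 without HA replicates 1, 2 and 3. It was also 9, 6 and 37 without coacervate replicates 1, 2 and 3, which lie outside the comparison.

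No gene passed the edgeR test between coacervate-treated and healthy cartilage, where 552 had an unadjusted p under 0.05, limma called 0 and DESeq2 called 18. The smallest adjusted p was 0.232. Sfrp2, a secreted modulator of Wnt signals, was at 1.25 ± 0.23 (adjusted p = 0.467) and the osteoclast phosphatase gene Acp5 at -0.85 ± 0.18 (adjusted p = 0.696). Of the 72 genes of the disease change, 61 kept its sign here, 14 passed adjusted over the list alone and 0 over all genes, and the choice of these genes on the same healthy libraries favours that sign. No test compared this count of 0 with the 23 of HA-treated cartilage. Between the treatments no gene passed over all genes, while 45 of the 72 passed adjusted over the list alone, each opposite to the disease change. Camera called 13 lists and 0 with an estimated correlation.

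Both treatments were compared with the same osteoarthritic libraries, which makes their differences alike by chance. At an unadjusted p under 0.01 in edgeR, the treatments shared 25 of 72 (HA) and 400 (coacervate) higher genes and 24 of 53 and 592 lower genes. No simulation was run for edgeR. In limma they shared 13 of 36 and 82 higher genes but only 1 of 19 and 170 lower genes. Simulations with no effect, also in limma, shared 4.86 higher and 5.18 lower genes. With the osteoarthritic libraries divided between the comparisons, limma gave 2.67 higher and 0.5 lower genes shared on average. Independent comparisons would share 8.83 and 11.2, so the divided counts lay below independence. A division can put osteoarthritic replicates 2 and 3, which stood apart, on the same side, which pushes the comparisons in opposite directions. The divided counts therefore cannot tell whether the treatments shared changes. The covariance across genes of the disease change with the change after treatment was -0.125 for the coacervate and -0.0607 for HA. Simulations with no effect and undivided libraries averaged -0.0468, so sharing alone gives a negative value. With the osteoarthritic libraries divided the covariance averaged -0.0593 (SD 0.0578 over 6 divisions) and 0.00473 (SD 0.0567). Simulations with no effect, divided in the same way, averaged -0.00771, and 5% of them lay below -0.0492. All these simulations drew libraries of any group into the shared role. The osteoarthritic libraries, of which replicates 2 and 3 stood apart, varied more than those of the other groups. The simulations can therefore understate what sharing alone gives, and they do not place either covariance beyond chance.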

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

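The tests of red cells, B cell precursors, random carry-over, a single source of muscle RNA and macrophage share, and the counts of other splits of the libraries, were chosen only after the results were seen. The tests of gene length and of dilution by muscle RNA were written down first.

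Osteoarthritic replicates 2 and 3 held more ribosomal protein, oxidative phosphorylation and haemoglobin transcripts than the other 14 libraries, with oxidative phosphorylation levels of 0.79 and 0.72 on the log2 scale. In both, short genes were higher relative to long ones (Spearman's rho with gene length across genes, which are not independent replicates, of -0.527 and -0.498, against -0.202 to 0.39 in the other 14). Taking a smooth trend on gene length out of each library lowered their ribosomal levels from 1.0 and 0.83 to 0.66 and 0.54, and the lower of these still lay 0.429 above the highest other library (SD 0.124), which counts against the length trend as the whole cause. More red cells as the whole source were argued against too, since the 14 erythroid genes other than haemoglobin lay at most 0.0924 above the mean of the other 14 libraries where haemoglobin lay 0.73 and 0.77 above it. A larger share of marrow with its B cell precursors may contribute and cannot be told apart, because the B cell level of at most -0.123 lay within the range of the other libraries. No biological explanation other than these was tested, and no group of the design separates these libraries from osteoarthritic replicates 1 and 4.

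Skeletal muscle transcripts were higher in the 4 coacervate-treated than in the 4 HA-treated libraries (mean log2 levels apart by 1.07, exact permutation p = 0.0286, the smallest possible). The 22 genes kept to a common pattern, with 66.2% of their variance over the 16 libraries along 1 axis and every weight of 1 sign, as 1 source of muscle RNA in differing amounts would give. Carry-over of muscle at random during dissection cannot be told apart from an effect of treatment, because the exact p adjusted over the 28 lists was 0.16 and 4 against 4 libraries cannot give a smaller unadjusted p. Coacervate replicate 3 alone held 2.75% muscle counts, against 0.811% to 1.39% in the other 3. The labels name no muscle and no dissection step, and a change of gene expression in cartilage itself was not tested.

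The 56 genes raised between healthy and osteoarthritic cartilage lay mostly lower in the coacervate-treated than in the HA-treated libraries (median -0.607), and the 16 lowered genes had a median of 0.238. Dilution by the transcripts of the muscle list was argued against, since their share of counts lowers all other transcripts by only -0.0119 on the log2 scale. Other RNA that muscle may bring was not measured. A lower share of macrophages cannot be told apart from lower expression within cells. The 20 macrophage genes outside the called genes had a median of -0.256 (SD 0.351, 14 of 20 negative), while 55 of the 56 raised genes were negative (SD 0.574), and a difference caused by the treatment itself stays open beside it.

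Other divisions of the same 8 libraries into 4 and 4 were fitted for each comparison, 35 in all with the real one. For osteoarthritic against healthy only 1 of 35, the real one, gave as many as 72 genes (highest other 22). For HA-treated against healthy only 1 gave as many as 23 (highest other 0). No smaller share can come from 35 divisions, and these shares were not adjusted over the comparisons. They argue against chance for both counts but do not exclude it. For the coacervate against osteoarthritic cartilage 3 of 35 gave at least 21 genes, with 4170 in the highest other, so chance cannot be excluded. The real count was 0 in HA-treated against osteoarthritic cartilage (highest other 4375), in coacervate against HA (highest other 1) and in coacervate against healthy (highest other 0). Every division gives at least 0 genes, so all 35 reached that count by necessity and the divisions say nothing about chance there. In these 3 comparisons edgeR gave 909, 1485 and 552 genes at an unadjusted p under 0.05, and DESeq2 called 8, 325 and 18. The divisions with 4375 and 4170 genes set osteoarthritic replicates 1 and 4 against 2 and 3, and a further one with 1752 set replicate 1 and 3 coacervate libraries against the rest, which points to a structure of the samples. For gene lists called with the preset correlation, chance cannot be excluded in any comparison. As many lists were called in 12 of 35 divisions for osteoarthritic against healthy (12 lists, highest other 17), 30 for HA-treated (7, highest other 20) and 20 for coacervate-treated against osteoarthritic (13, highest other 20). The numbers were 9 for coacervate against HA (15, highest other 18), 17 for HA-treated (10, highest other 14) and 15 for coacervate-treated against healthy (13, highest other 21).

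Single libraries far from the other 3 of their group were found in 24 of 420 groups of values, where chance gives about 1 in 20, or 21. Healthy replicate 3 had fewer counts (36988722 against at least 47570829), more Col1a1 (12400 CPM against at most 8240), more Sox9 (12.8 against at most 7.15) and more Hspa5 (741 against at most 565). Healthy replicate 4 had more Ccl7 (1.26 against at most 0.749 CPM) and less Rps18l1 (22.1 against at least 25.8). Osteoarthritic replicate 4 had more Apoe (2650 CPM against at most 1390) and a B cell level of -0.946 against -0.147 to -0.107. Osteoarthritic replicate 1 had an interferon response level of -0.59 against 0.126 to 0.272, less Apold1 (13.4 against at least 16.5 CPM), Clec4a2 (6.26 against at least 10.1), Fabp5 (42.6 against at least 61.6) and Rps27a (65.7 against at least 119), and more Gp5 (28.1 against at most 18.8).

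HA replicate 1 had a lower haemoglobin share (11.1% against 12.3% to 12.5%), HA replicate 2 more Ctsl (308 CPM against at most 211) and Scimp (21.3 against at most 9.2), and HA replicate 3 more Col2a1 (3070 against at most 2080) and less Gimap4 (8.48 against at least 10.6). Coacervate replicate 1 had more Fabp5 (34.5 CPM against at most 23) and Il1b (18.6 against at most 10.3) and less Cx3cr1 (3.54 against at least 4.48). Coacervate replicate 3 had more Dpt (138 against at most 68.6) and Hspa5 (607 against at most 519).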

How the results depend on the processing

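DESeq2, limma at a pseudocount of 1, the settings without osteoarthritic or coacervate replicates 2 and 3, without haemoglobin genes, with the ribosomal protein level as a covariate and with sample weights estimated gene by gene, and the term tests under each alternative, were chosen after seeing the data. Of 2226 values of named genes under alternatives, 1810 kept their side of the threshold, 352 lost it, 59 passed it and 5 reversed, and of 3920 list values 3557 kept it, 219 lost it, 105 passed it and 39 reversed. The sign of a list value was first taken from the direction of camera, and taking it from the mean of the list was settled after the values had been seen, which changed the lists that count as reversed. The counts of genes rest on a threshold near which many genes lie, and the smallest adjusted p ranged from 0.0115 to 0.562 over the comparisons. Apart from the fold cutoff, which can only remove genes, the cause of each difference below was not tested. The median log2 fold change of all genes was -0.0109 in HA against osteoarthritic cartilage and 0.0149 in osteoarthritic against healthy. Under scaling to the library total these were 0.104 and -0.0856, and in limma at a pseudocount of 1 they were 0.12 and -0.108.

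For osteoarthritic against healthy (72 genes) the count was 40 with a fold cutoff, 418 in DESeq2, 8 with the 2 groups alone, 28, 21 and 12 in limma at pseudocounts of 0.1, 1 and 5, 0 with REML sample weights, 45 with no filter, 26 with the replicate block, 351 with the ribosomal covariate, 29 with library totals and 164 without osteoarthritic replicates 2 and 3, among which were 40 of the 72. For the coacervate against osteoarthritic (21 genes) it was 8 with a fold cutoff, 797 in DESeq2, 3 without osteoarthritic replicates 2 and 3, and 1 each with no trend and with robust fitting. It was 0 with the 2 groups alone, limma at 0.1, 1 and 5, REML weights, no filter, the replicate block, library totals and without coacervate replicates 2 and 3. For HA-treated against healthy (23 genes) it was 159 in DESeq2, 390 with the 2 groups alone, 15, 14 and 3 in limma at 0.1, 1 and 5, 12 with quantile scaling, 226 with REML weights, 12 with no filter, 15 with no trend, 0 with the replicate block, 276 with the ribosomal covariate and 94 without osteoarthritic replicates 2 and 3. From 0 genes, coacervate against HA went to 325 in DESeq2, 198 with REML weights, 130 with the ribosomal covariate and 149 without osteoarthritic replicates 2 and 3. HA against osteoarthritic went to 8 in DESeq2 and 1 in limma at 0.1, at 1 and with quantile scaling, and coacervate against healthy to 18 in DESeq2.

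The REML sample weights in limma stopped before convergence, and limma's gene-by-gene estimate gave very different counts, so neither is a firm value. Gene by gene, osteoarthritic replicates 1 and 4 weighed 0.139 and 0.135 against 0.849 and 1.94 for replicates 2 and 3, and the counts were 7137 (osteoarthritic against healthy), 6453 (HA) and 6931 (coacervate against osteoarthritic), 166 (coacervate against HA) and 207 (HA against healthy), with 29 lists and 1505 terms. Reversed values under them were, in osteoarthritic against healthy, Acan -0.975, Col1a1 -0.876, Col2a1 -0.795 and, as list means, -0.0937 (fibrous matrix), -0.0366 (secretory pathway, and -0.000824 with REML weights) and -0.0778 (tendon). They were Adamts5 0.589 in HA against osteoarthritic, and Acan 0.91 and the proteases 0.0699 in coacervate against osteoarthritic.

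With 1 library of the compared groups left out the counts ranged from 15 to 1122 (osteoarthritic against healthy), 0 to 2054 (coacervate against osteoarthritic), 0 to 31 (HA against healthy), 0 to 11 (coacervate against HA), 0 to 1 (HA against osteoarthritic) and 0 to 1 (coacervate against healthy). Osteoarthritic against healthy gave 23, 15, 18 and 15 genes without healthy replicates 1 to 4, 1122 without osteoarthritic replicate 1 and 25 without replicate 3. Coacervate against osteoarthritic gave 2054 without osteoarthritic replicate 1, 1368 without replicate 4, and 0 without replicate 2 or 3 or any coacervate library. HA against healthy gave 14, 1 and 0 without HA replicates 1, 2 and 3, and 2, 0, 2 and 0 without healthy replicates 1 to 4. Coacervate against HA gave 11 without HA replicate 4, HA against osteoarthritic 1 without osteoarthritic replicate 4, and coacervate against healthy 1 without coacervate replicate 4. Libraries outside a comparison moved 3 counts. Osteoarthritic against healthy went to 44 without HA replicate 1 or 3 and to 38 and 36 without coacervate replicates 1 and 2. Coacervate against osteoarthritic went to 0 without any healthy library or HA replicate 1, and to 1 and 7 without HA replicates 3 and 4. HA against healthy went to 9, 6 and 37 without coacervate replicates 1, 2 and 3. The called lists (47 over 4 comparisons) ranged from 43 to 51, and were 0 with an estimated correlation and 1 with fry. The 16 called terms ranged from 0 to 214 with 1 library left out: 1, 0, 4 and 1 without healthy replicates 1 to 4, 214, 5 and 89 without osteoarthritic replicates 1, 3 and 4, 6, 7 and 1 without HA replicates 1 to 3, and 3 and 2 without coacervate replicates 1 and 2. They were 128 in DESeq2, 6 and 8 in limma at 0.1 and 5, 47 with REML weights, 7 with no filter, 2 with the replicate block, 159 with the ribosomal covariate, 6 with library totals and 83 without osteoarthritic replicates 2 and 3. The difference in disease score between coacervate and HA ranged from -0.966 to -0.421 with 1 library left out, with p = 0.0571 in exact permutation tests without coacervate replicates 1, 2 or 4. It was -0.475 without osteoarthritic replicates 2 and 3, and -0.84 in the replicate block (exact p = 0.125). Replicate numbers did not pair the libraries, since correlations of same-numbered libraries across genes ran from -0.39 to 0.21 over 24 pairs and 3 of them exceeded 0.1. The overlap of the treatments was 49 at an unadjusted p under 0.01. On genes called in the part of the libraries used, the shift along the disease change was -0.207 (coacervate) and -0.141 (HA). No simulation with no effect was run on such genes, so these values cannot be read as a shift beyond the choice of genes.

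Choices of processing, beside the estimated correlation and fry, also ended calls of lists by camera. A stricter filter ended T cell and NK cell genes in 3 comparisons, adipocyte genes in osteoarthritic against healthy, endothelial and inflammatory genes in coacervate against osteoarthritic, and adipocyte, cartilage matrix, endothelial, immediate early, osteoclast and ribosomal protein genes in coacervate against HA. Quantile scaling ended antioxidant genes in 3 comparisons, neutrophil, secretory and tendon genes in osteoarthritic against healthy, erythroid and ribosomal protein genes in HA against osteoarthritic, endothelial, oxidative phosphorylation and secretory genes in coacervate against osteoarthritic, and osteoclast and ribosomal protein genes in coacervate against HA. The ribosomal covariate ended antioxidant genes in 3 comparisons, neutrophil genes in osteoarthritic against healthy, adipocyte, ribosomal protein and T cell and NK cell genes in HA against osteoarthritic, endothelial genes in coacervate against osteoarthritic, and immediate early and T cell and NK cell genes in coacervate against HA. Library totals and limma at 0.1, 1 and 5 each ended endothelial genes in coacervate against osteoarthritic and osteoclast genes in coacervate against HA, and limma at 5 also cartilage matrix genes there. No filter ended immediate early genes in coacervate against HA, and leaving out haemoglobin genes ended erythroid and T cell and NK cell genes in HA against osteoarthritic. Of 35 alternatives, the most that ended 1 call were 16 (endothelial, coacervate against osteoarthritic), 13 (osteoclast) and 12 (immediate early, both in coacervate against HA).

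Mean log2 fold changes of lists that reversed without osteoarthritic replicates 2 and 3 were, in osteoarthritic against healthy, -0.251 (ribosomal), -0.233 (oxidative phosphorylation), -0.0545 (neutrophil) and -0.0716 (antioxidant). In HA against osteoarthritic they were 0.375 (ribosomal), 0.251 (oxidative phosphorylation), 0.337 (neutrophil), 0.0926 (antioxidant), 0.017 (adipocyte), 0.00291 (T cell and NK cell), -0.189 (cartilage matrix), -0.148 (endothelial), -0.32 (fibrous matrix) and -0.187 (proteases). In the coacervate against osteoarthritic they were 0.241 (ribosomal), 0.237 (oxidative phosphorylation), 0.0695 (antioxidant) and 0.303 (adipocyte). With the ribosomal level as a covariate, which removes that list's own change, the ribosomal list was at -0.00575 (osteoarthritic against healthy), 0.005 (coacervate against osteoarthritic) and 0.00545 (coacervate against HA), oxidative phosphorylation at -0.0015, 0.0245 and 0.102 in these, and neutrophil genes at 0.121 (HA against osteoarthritic). Without coacervate replicates 2 and 3, coacervate against HA gave -0.0133 (endothelial), 0.0392 (ribosomal) and -0.236 (tendon), and coacervate against osteoarthritic -0.0234 (endothelial) and -0.303 (tendon). With no filter, endothelial genes were at -0.131 (coacervate against HA) and -0.25 (coacervate against osteoarthritic). With 1 library left out, neutrophil genes in HA against osteoarthritic ranged from -0.307 to 0.119 (without osteoarthritic replicate 2), and adipocyte genes in osteoarthritic against healthy from -0.416 to 0.00566 (without osteoarthritic replicate 4). Leaving out haemoglobin genes, size factor scaling and a stricter filter kept the counts of called genes within 1.5 times.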

Other observations

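Lists of genes were also compared between healthy cartilage and each treated group, where camera at the preset correlation called lists and no call held with an estimated correlation. Of 28 fibrous matrix genes, 28 were higher in coacervate-treated cartilage (median 0.44, camera adjusted p = 9.62e-15, and adjusted p = 0.235 with an estimated correlation) and 26 in HA-treated cartilage (median 0.55, adjusted p = 2.02e-16, and adjusted p = 0.209 with an estimated correlation), where 4 and 11 rose adjusted over the list alone and 0 and 1 over all genes. Tendon and ligament genes had medians of 0.48 and 0.37 (adjusted p = 8.12e-09 and 0.000955, and adjusted p = 0.235 and 0.6 with an estimated correlation), with 4 and 3 risen adjusted over the list alone. Proteases had a median of 0.39 in HA-treated cartilage, with 10 of 25 risen adjusted over the list alone (adjusted p = 1.45e-14, and adjusted p = 0.207 with an estimated correlation), and 0.18 with 0 risen in coacervate-treated cartilage (adjusted p = 0.00129, and adjusted p = 0.557 with an estimated correlation). Without coacervate replicate 3 the coacervate medians were 0.19 (fibrous matrix) and 0.25 (tendon), and camera did not call the proteases (0.055, adjusted p = 0.093). Skeletal muscle genes were also called in coacervate-treated against healthy cartilage (median 0.424), and camera did not call them without coacervate replicate 3 (-0.0719, adjusted p = 0.144).

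Neutrophil genes lay above healthy cartilage in 21 of 21 with HA (median 0.28, camera adjusted p = 3.88e-05, and adjusted p = 0.574 with an estimated correlation) and below it in 21 of 21 with the coacervate (median -0.34, adjusted p = 8.12e-09, and adjusted p = 0.245 with an estimated correlation). Osteoclast genes had a median of -0.27 in coacervate-treated against healthy cartilage, with 4 fallen and 1 risen adjusted over the list alone (adjusted p = 1.53e-08, and adjusted p = 0.235 with an estimated correlation). T cell and NK cell genes were lower in 14 of 15 there (median -0.33, adjusted p = 8.46e-07, and adjusted p = 0.235 with an estimated correlation), and proliferation genes higher in 27 of 29 (0.15, adjusted p = 1.34e-07, and adjusted p = 0.409 with an estimated correlation). These medians were -0.13 (osteoclast) without healthy replicate 4, -0.515 (T cell and NK cell) without coacervate replicate 4 and 0.068 (proliferation) without coacervate replicate 1. Adipocyte genes were lower in 19 of 19 with HA (median -0.47, adjusted p = 2.66e-10, and adjusted p = 0.209 with an estimated correlation), with 4 fallen adjusted over the list alone. On the second principal component (12% of the variance) the coacervate libraries lay at 8 to 11.7 and the healthy ones at 12.3 to 21. The HA libraries lay at -26.5 to -4 and osteoarthritic replicates 1 and 4 at -15.6 and -31, while osteoarthritic replicates 2 and 3 lay at 1.3 and 5.5.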
